A study of Mus musculus with 2 samples.

How the data were processed

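H3K36me3 ChIP-seq peak lists from mouse midbrain at 16.5 days of development were analysed, 1 list for each of 2 biological replicates and 2 lists made from both. Per the labels, both replicates were mixed-sex pools, and replicate 2 held 37 embryos and 2 technical replicates. Coordinates are on mm10, per the labels. The listing deposited with the files gave the origin of each list. Each replicate list was made from that replicate's own alignments and 2 further files of unstated kind, the pooled list from both replicates' alignments, and the replicated list from the other 3 lists. The rule that selected the replicated peaks, the aligner and the peak caller with its settings were not given in the sources used here, and the labels name a possible control experiment that was not used here.

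Each deposited list gave per peak a fold enrichment, a linear ratio over the caller's background. The −log10 p-value and −log10 q-value of each peak are likewise the authors' own deposited values. The lowest −log10 p was 2.01 in both replicate lists, so no listed peak had p above 0.01. A deposited display score and a summit offset were not used. Fold, p and q served to describe and filter peaks, to compare fold between replicates, to weight gene coverage by fold and to solve for fragment numbers. Read totals per sample were not given in the sources used here. Each replicate peak's fold and p were solved as (n + 1)/(b + 1) and the Poisson tail of n at mean b, where n is a whole number of fragments and b the background. A solution within 0.001 of the deposited −log10 p was found for 100% of peaks in both replicates and for 0.168% of the pooled list, whose values were therefore not treated this way. The relation was inferred from the values and is stated in no source used here.

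Gene bodies were the 21196 protein-coding genes of GENCODE M21 (GRCm38) of at least 1 kb on chromosomes 1 to 19, X and Y, 1 per symbol, from the first to the last annotated base. No peak ran past a chromosome end of the reference. Coverage was the percent of the body under peaks, given as mean ± SD over 2 replicates. A gene was marked at 20% or more in each replicate. Peaks were called shared when at least 50% of their length was covered. Shares of peak bases were compared with 1000 circular shifts of each list along each chromosome, one-sided. The 3′ against 5′ comparison (genes of at least 10 kb), the 5 kb flanks (no other gene within 10 kb) and the internal exon against intron comparison (at least 3 exons, first exon and first intron left out) used two-sided exact sign tests over chromosomes with at least 10 genes, or 5 for flanks. Gene lists were compared by their median with 10000 random lists, each member being replaced by a random gene from the 200 nearest in length outside the list, which gives a Monte Carlo permutation test of list membership, two-sided, with Benjamini-Hochberg adjustment over 29 lists and a threshold of 0.05. Domains were peaks stitched across gaps of up to 3 kb. With 1 group, no test between groups was made, and tests over chromosomes or genes do not measure the spread between animals.

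The designs, gene lists and rule for named genes were fixed before the data were examined. Named were up to 2 members with the highest and 2 with the lowest coverage of each list, the 10 genes of at least 5 kb with the highest coverage and the 10 with the highest length-normalised fold, the genes of the 10 longest domains seen in both replicates, up to 5 intergenic domains, and the 5 genes with the largest gap between replicates in each direction. In lists with a median of 0%, members of this rule at or near 0% were not all printed. Length-normalised fold is the sum of fold times overlapped bases, divided by body length. Alternatives were a −log10 q of at least 2, other overlap and coverage minimums, the pooled and replicated lists, each replicate left out, other flanks and stitching gaps, genes without overlaps and length-normalised fold. List means (also with GC matching and with each replicate left out), GC matching, autosomes alone, the histone list without H13, H3f3a and H1f0, and the alternatives for gene length were added after seeing the data. GC content came from the GRCm38.p6 sequence.

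The 3′ against 5′, exon against intron, peak base and gene list steps were tested on simulated data. The flank, replicate overlap, fold correlation, domain and replicate difference steps were not. List means and lists with lowered coverage were not simulated either. With no preference, the 3′ difference over 2000 genes was −0.213 points, and 60% of peaks placed in the 3′ part gave 9.02 points. For exons against introns it was −1.08 points with no preference, a small bias toward introns. Of 20 unchanged lists 1 was called by the shift test. Of 200 random gene lists 11 were called unchanged and 175 when raised by 10 points. Of 100 lists driven by simulated GC alone, 100 were called with length matching and 6 with length and GC matching. Last exons of zinc finger genes were searched against the genome with BLAST 2.17.0 (95% identity over 200 bases, repeats in the query masked). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on unplaced scaffolds (40 in replicate 1 and 37 in replicate 2) stayed in the peak counts, fragment numbers, peak overlap and fold comparison. They were left out of the shift, gene and domain comparisons. Noncoding genes entered through the bases in or outside any annotated gene and the search for neighbouring genes around flanks.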

Results

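Chromatin immunoprecipitation sequencing (ChIP-seq) with an antibody against H3K36me3, a trimethylated form of histone H3, was carried out on midbrain of mouse embryos at 16.5 days. This mark is laid down by SETD2 over the bodies of genes transcribed by RNA polymerase II. The data formed 1 group of 2 biological replicates from mixed-sex pools of strain B6NCrl, and no other tissue, age or treatment entered the comparisons. Per the labels, replicate 2 joined 37 embryos and 2 technical replicates. The labels gave 1 technical replicate for replicate 1, and its number of embryos was not given in the sources used here. The questions addressed were where the mark lay, which genes and gene groups carried it, and how far both replicates shared it. Replicate 1 had 162395 peaks covering 55.6 Mb and replicate 2 had 165098 peaks covering 56.9 Mb, or 163746 ± 1911 peaks (SD, n = 2). Read totals were not given in the sources used here. The deposited fold and p of each peak solved to whole fragment numbers for all 162395 and 165098 peaks, within 0.001 on the −log10 p scale. The median was 12 fragments at a summit over a most frequent background of 2.32 in replicate 1, and 11 over 1.83 in replicate 2. Peak positions and fold values rested on these small fragment numbers.

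Both replicates covered largely the same genes and broad domains, while single peaks were shared less fully. Coverage of gene bodies by peaks had a Spearman's rho of 0.932 and a Pearson's r of 0.935 between replicates across 21196 protein-coding genes, which are not independent replicates. Both correlations included 9117 genes (43.01%) with 0% in both replicates. Of domains of 10 kb or more, 94.2% in replicate 1 and 92.5% in replicate 2 were covered over 50% or more of their length by domains of the other replicate. Of single peaks, 46.4% in replicate 1 and 45.2% in replicate 2 had at least 50% of their length under peaks of the other, or 45.8% ± 0.823 (SD, n = 2). Lists shifted along each chromosome shared 2.38% on average, and none of the 1000 shifts reached the observed share (one-sided permutation p = 0.001, the smallest the shifts can give). The shared percentage depended on the overlap asked for, with 28.8% when 50% of both peaks had to overlap. Across the 98962 peaks of replicate 1 that overlapped a replicate 2 peak, fold values had a Spearman's rho of 0.237 and a Pearson's r of 0.265 on the log2 scale, as a relation across peaks. Fold was higher in replicate 2 at 67.8% of them. Each was compared with the strongest replicate 2 peak it overlapped, a rule that favours replicate 2. The submitters' replicated list held 102057 peaks, each identical in position to a peak of their pooled list of 139824. Peaks of both replicates covered at least 50% of the length of 72.3% of the replicated peaks.

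Peaks lay almost entirely within genes and avoided promoters. Protein-coding gene bodies held 94.1% ± 0.629 of peak bases (SD, n = 2), against 42.0% in shifted lists. Exons held 26.7% ± 1.19 of peak bases, 6.70 times the shifted share of 3.99%, and introns held 67.4% ± 0.561, against 38.0%. Stretches within 1 kb of a transcription start site (TSS) held 0.445% ± 0.0469, which was 0.262 times the shifted share of 1.70%. Bases outside any annotated gene made up 4.90% ± 0.497, against 51.1% in shifted lists. In each replicate, every one of these shares lay beyond all 1000 shifts in its direction (one-sided permutation p = 0.001, the smallest the shifts can give).

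A gene was called marked when peaks covered at least 20% of its body in each replicate, and 3064 of 21196 protein-coding genes (14.5%) were marked. Zinc finger protein genes led the ranking by coverage among genes of at least 5 kb. Zfp518b (chromosome 5, ending at 38684826, minus strand, mm10) had 81.1% ± 0.143 of its body under peaks (SD, n = 2), Zfp606 80.4% ± 4.38 and Zfp110 78.9% ± 3.84, with Zfp2, Zfp90 and Zfp68 next at 77.9%, 74.1% and 73.1%. Fasn, the fatty acid synthase gene, followed at 71.9% ± 4.60, then Ccdc177 at 71.2% ± 2.46, Gm49601 at 68.6% ± 18.4 and Polrmt, which encodes the mitochondrial RNA polymerase, at 68.1% ± 0.270. Ranking by length-normalised fold kept 8 of these 10 genes and added Repin1 and Zfp263, with values of 6.44 and 5.09. The strongest peak of Ccdc177 had a fold of 12.1 ± 9.71 (SD, n = 2). Gm49601 and Repin1 overlap another protein-coding gene, so the source of their coverage was uncertain. No peak of either replicate touched 9117 genes (43.01%). The marked count rested on the coverage asked for, with 5471 genes at 10% and 529 at 40%.

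Genes of intermediate length were marked most often. Of genes of 10 to 20 kb, 909 of 3999 (22.7%, 95% Wilson interval 21.5 to 24.1) were marked, and of genes of 20 to 50 kb 1106 of 5149 (21.5%, 20.4 to 22.6). The share was 5.85% of 3417 genes of 1 to 5 kb, 10.4% of 2513 genes of 50 to 100 kb and 0.401% of 997 genes over 200 kb. Genes over 200 kb had a peak in both replicates in 79.2% of cases, against 16.9% of genes of 1 to 5 kb, a share that a longer body can raise by itself. Mean coverage of genes over 200 kb was 1.69%, the lowest of any length bin, against 11.75% in genes of 10 to 20 kb. The neuronal gene Nrxn3, a presynaptic adhesion molecule spanning 1612060 bases, had 0.222% ± 0.0354 of its body under peaks (SD, n = 2). These intervals cover counting of genes only.

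X-linked and Y-linked genes were marked less often than those on every autosome. On the X chromosome 8 of 877 genes (0.912%) were marked and on the Y chromosome 0 of 163, whereas the autosomes ranged from 9.70% to 20.8% and had 3056 of 20156 genes marked (15.2%). Among all genes annotated on the X chromosome, whatever their copy number, Asmt had the highest coverage at 38.8% ± 14.5 (SD, n = 2), followed by Amer1 at 30.4% ± 0.156. Asmt encodes the last enzyme of melatonin synthesis. The ribosomal protein gene Rpl10 on the X chromosome had 0% in both replicates. Among Y-linked genes Kdm5d and Ddx3y were highest at 0.378% ± 0.115 and 0.338% ± 0.478. The test on medians did not separate Y-linked genes from random lists of the same lengths, since both had a median of 0%. Near-identical copies were searched for only among zinc finger genes, so their part in the low Y-linked coverage was not tested. X-linked genes had a median coverage of 0%, against 0.358% in random lists of the same lengths (adjusted p = 0.00644, two-sided permutation test with 10000 random lists, Benjamini-Hochberg over 29 lists). That call on medians was lost with either replicate alone, with stricter peaks, with the replicated list, among genes overlapping no other coding gene and with random lists matched on GC as well (adjusted permutation p from 0.938 to 1.00). With list means in place of medians, an alternative chosen after seeing the data, X-linked genes had 1.79% against 7.92% (adjusted permutation p = 3.05e-04).

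**Figure D1:**
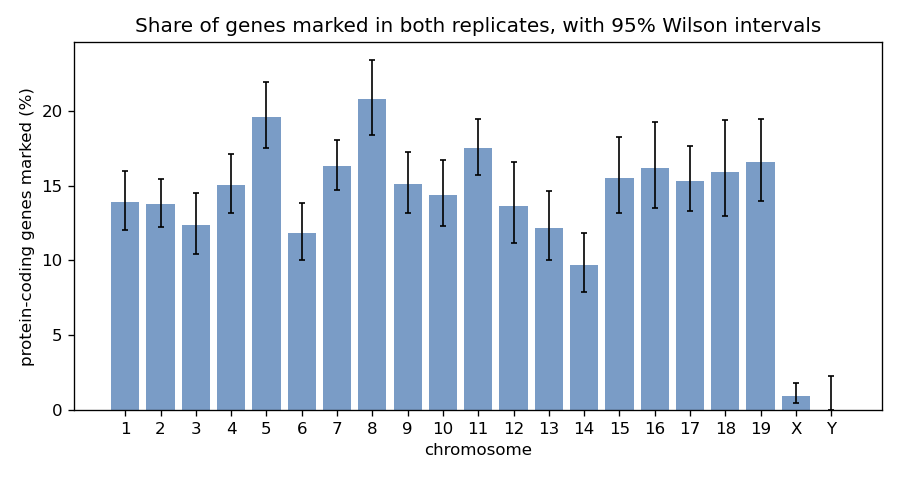
Bars give the percent of protein-coding genes marked in both replicates (y axis) on each chromosome (x axis), and error bars are 95% Wilson intervals over genes. Autosomes lie between 9.70% and 20.8%, the X chromosome at 0.912% and the Y chromosome at 0%.

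Within marked genes, coverage rose from the TSS toward the 3′ end and continued past it. Among 2334 marked genes of at least 10 kb, each body was split into 10 equal parts from the TSS. Mean coverage was 3.12% ± 0.143 in part 1 (SD, n = 2), 33.4% ± 1.04 in part 4, 47.8% ± 1.91 in part 9 and 43.5% ± 2.33 in part 10. The 3′ part of the body, split at its midpoint, exceeded the 5′ part by a median of 21.7 percentage points over genes, with 21.1 in replicate 1 and 21.6 in replicate 2. The difference was positive in 89.3% of genes and had a positive median on all 19 chromosomes tested (two-sided exact sign test over chromosomes, p = 3.81e-06). In 191 marked genes with no other annotated gene within 10 kb, the 5 kb after the gene end were 13.2% ± 1.17 covered and the 5 kb before the TSS 0.0818% ± 0.0286 (SD, n = 2). The mean difference was positive on all 17 chromosomes tested (two-sided exact sign test, p = 1.53e-05). It was 24.6 points with flanks of 2 kb and 7.33 points with flanks of 10 kb.

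**Figure D2:**
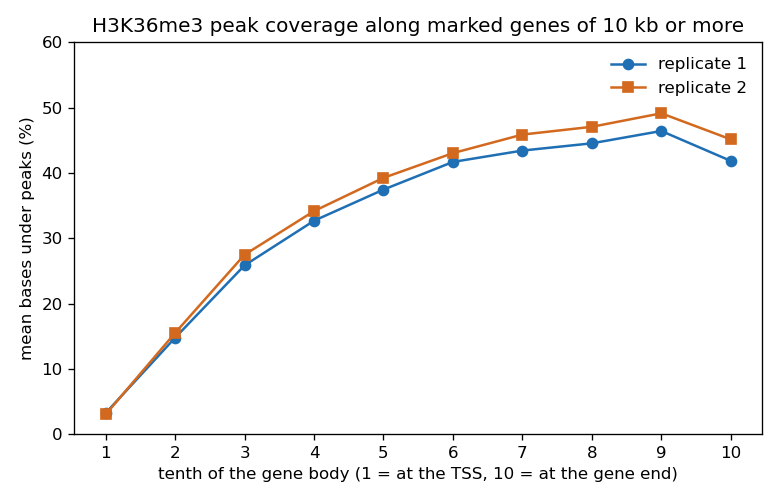
Mean percent of bases under peaks (y axis) in each of 10 equal parts of the gene body from TSS to gene end (x axis) over 2334 marked genes of at least 10 kb, with 1 line per replicate. Both lines rise from 3.22% and 3.02% in part 1 to 46.4% and 49.1% in part 9.

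Internal exons carried more coverage than introns of the same genes, with a smaller difference where exon and intron GC were alike. Over 2934 marked genes with at least 3 exons, internal exons were 48.4% covered in replicate 1 and 54.1% in replicate 2, and introns 38.5% and 40.3%. The median difference within genes was 13.8 percentage points, with 12.0 in replicate 1 and 15.8 in replicate 2, and it was positive on all 19 chromosomes tested (two-sided exact sign test, p = 3.81e-06). Internal exons had a median GC content of 52.2% and introns of 45.9% across 2952 marked genes with both values. In 346 genes whose exon and intron GC lay within 2 points, an alternative chosen after seeing the data, the median difference was 5.95 points and positive on all 16 chromosomes tested (exact sign test p = 3.05e-05). In 176 genes whose exon GC was no higher than intron GC it was −0.598 points, a value without a usable test, since only 5 chromosomes held enough such genes.

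Gene groups used by nearly every cell were widely marked. Splicing factor genes had 33 of 53 members marked and a median coverage of 27.5%, led by Prpf8, a core protein of the spliceosome, at 63.4% ± 2.68 and Hnrnpul1 at 59.0% ± 2.40 (SD, n = 2), while Sf3b5 had 0% and Hnrnpf 0.383% ± 0.542. Proteasome and RNA polymerase II subunit genes had 30 of 52 marked and a median of 26.6%, with Polr2m at 53.6% ± 5.73 and Psmc4 at 51.2% ± 5.23. Polr2i, an RNA polymerase II subunit gene, and Psma8, a proteasome subunit of the testis, had 0%. Cytosolic ribosomal protein genes had 31 of 81 marked and a median of 19.1%, with Rpl23 at 48.4% ± 1.44 and Rpl27 at 44.7% ± 6.76, and with Rpl10 and Rpl10l at 0%. Genes of the mitochondrial respiratory complexes had 28 of 76 marked and a median of 17.9%, with Uqcrc1 at 54.0% ± 0.599 and Atp5a1, which overlaps another protein-coding gene, at 53.0% ± 4.16. Their lowest members, Atp5k and Cox6b2, had 0%. All 4 lists lay above 10000 random lists matched on gene length, whose medians centred on 0% to 0.850% (adjusted p = 9.67e-04 each by the permutation test, Benjamini-Hochberg over 29 lists, from p = 0.0002, the smallest the random lists can give). Such a test describes these libraries across genes, which are not replicates.

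Genes that write, erase or read H3K36 methylation had 8 of 23 measured members marked and a median of 19.4%, against 2.34% in random lists (adjusted permutation p = 0.00249). Kdm4a, a demethylase of H3K36 and H3K9, had 57.5% ± 5.71 of its body covered and Glyr1, a chromatin protein of transcribed genes, 48.0% ± 0.163 (SD, n = 2). Phf19, a Polycomb-associated protein, had 0%, and the DNA methyltransferase gene Dnmt3b 2.89% ± 2.47. Cell cycle genes had 3 of 22 marked, with the replicative helicase gene Mcm4 at 34.8% ± 1.46 and the ribonucleotide reductase gene Rrm1 at 27.5% ± 6.22, while Aurkb and Ccnb1 had 0%. Their median of 1.77%, with 0.979% in replicate 1 alone and 3.41% in replicate 2 alone, did not pass the test (adjusted permutation p = 1.00).

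Pan-neuronal genes carried the mark at low to moderate coverage, whereas lists of genes of particular neuron types had no marked member. All 30 pan-neuronal genes had a peak in both replicates, 4 were marked, and the median was 7.43%, against 0.762% in random lists (adjusted permutation p = 0.00363). Kif1a, a motor of axonal transport, had 51.2% ± 8.01 and the neurofilament gene Ina 30.7% ± 5.42 (SD, n = 2), although Ina overlaps another protein-coding gene. Rbfox3, spanning 421836 bases, had 0.429% ± 0.189. Of 20 midbrain dopaminergic neuron genes 0 were marked and 2 had a peak in both replicates. Their highest members were Slc18a2, the vesicular monoamine transporter, at 0.8002% ± 1.13 and the receptor gene Ret at 0.630% ± 0.891, and Aldh1a1 and Chrna6 had 0%. None of 32 other midbrain neuron and patterning transcription factor genes was marked, with Sall3 and Lhx1 highest at 1.38% ± 0.544 and 1.17% ± 1.66 and Barhl2 and Gata2 at 0%. Neurotransmitter synthesis and transport genes had 0 of 15 marked, led by Slc17a6, the vesicular glutamate transporter, at 5.48% ± 0.936 and Gad1, a GABA-synthesising enzyme, at 4.06% ± 0.594, with Chat and Dbh at 0%. The medians of these 3 lists were 0% and did not pass the test (adjusted permutation p = 0.308, 0.772 and 0.592). With list means, an alternative chosen after seeing the data, all 3 fell below random lists at 0.131% against 8.35%, 0.194% against 7.40% and 0.810% against 8.94% (adjusted permutation p = 3.05e-04, 3.05e-04 and 5.80e-04). Peaks describe the midbrain as a whole. Low coverage of these lists, or of the other cell type lists below, therefore does not show that the mark was absent from a small share of cells.

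Progenitor and glial genes gave few marked members. Radial glia and progenitor genes had 0 of 21 marked. Msi1, an RNA-binding protein of neural progenitors, had 22.6% ± 11.9, and Vim 6.40% ± 2.78 (SD, n = 2), while Ascl1 and Fabp7 had 0%. Astrocyte genes had 0 of 14 marked, with Apoe at 0% in replicate 1 and 17.8% in replicate 2, Clu at 5.64% ± 5.95 and Aldh1l1 and Aldoc at 0%. Oligodendrocyte lineage genes had 1 of 15 marked, Cnp at 39.4% ± 8.203, and Cnp overlaps another protein-coding gene. Mog had 13.7% ± 6.49, and Cspg4 and Gpr17 0%. Microglia and leukocyte genes had 1 of 16 marked, Cd68 at 47.4% ± 15.3 in a body of 1941 bases, which fell to 16.98% with only peaks of −log10 q of at least 2. Cx3cr1, which overlaps another protein-coding gene, followed at 8.98% ± 0.7997, while Aif1 and C1qa had 0%. None of these 4 lists passed the test on medians (adjusted permutation p = 1.00 each). With list means the astrocyte list alone among them passed, at 1.76% against 8.53% (adjusted permutation p = 0.0194), and without replicate 1 it did not (adjusted permutation p = 0.0522). With means and random lists matched on GC as well, the radial glia and oligodendrocyte lists also fell below (adjusted permutation p = 0.0109 and 0.0434).

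Lists of forebrain, Hox, vessel, blood, other tissue and receptor genes had no marked member. Forebrain transcription factor genes (20), Hox genes (39), endothelial and pericyte genes (16), erythroid genes (14 measured), liver genes (19), muscle genes (20), olfactory receptor genes (1069), vomeronasal receptor genes (272) and keratin genes (70) each had 0 marked members and a median of 0%, although 4 of the 16 endothelial and pericyte genes had a peak in both replicates. Bcl11b was highest among forebrain factors at 2.35% ± 0.230 (SD, n = 2), Slc2a1, the glucose transporter of the blood-brain barrier, among endothelial and pericyte genes at 8.39% ± 7.42, Epb42 and Alas2 among erythroid genes at 3.70% ± 0.461 and 3.42% ± 1.42, and Ttn among muscle genes at 4.39% ± 0.608. Alas2 overlaps another protein-coding gene, so the source of its coverage was uncertain. Pdgfrb had 1.81% ± 1.87, Olfr543 6.54% ± 4.53, Olfr544 3.47% ± 0.248 and Vmn1r66 1.87% ± 2.65. All 19 liver genes, Alb and Afp included, had 0% in both replicates. None of these 9 lists passed the test on medians, which had no room below 0% (adjusted permutation p from 0.162 to 1.00). With list means each of the 9 lay below random lists matched on length (adjusted permutation p from 3.05e-04 to 0.00501), on length and GC (p up to 0.00414) and with either replicate left out (p up to 0.00832).

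Zinc finger protein genes formed the largest widely marked family, with 173 of 418 members marked and a median of 19.5%, against 1.42% in random lists (adjusted permutation p = 9.67e-04). Zfp114 and Zfp185 had 0%. Clustered protocadherin genes, neuronal adhesion molecules, had 14 of 56 marked and a median of 8.23%, against 0.449% (adjusted permutation p = 9.67e-04). Pcdhga3 and Pcdhgb1 had 33.6% ± 5.68 and 33.3% ± 5.38 (SD, n = 2), but all 56 overlap other protein-coding genes, so these values were not independent of each other. The list could not be tested among genes free of overlap. Imprinted protein-coding genes had 3 of 23 marked, with Igf2r, the receptor that clears Igf2, at 28.9% ± 4.30 and Nnat at 54.7% ± 0.434, while Cdkn1c and Dlk1 had 0%, and their median of 4.10% did not pass the test (adjusted permutation p = 0.551). The median of the imprinted list was 5.84% in replicate 1 alone and 2.36% in replicate 2 alone. Nnat overlaps another protein-coding gene, so the source of its coverage was uncertain. The symbol pattern for replication-dependent histone genes took 23 genes, of which H13, a signal peptide peptidase gene that overlaps another coding gene, and H3f3a, a replacement histone gene, were the 2 marked, at 39.6% ± 4.19 and 35.2% ± 2.04. The list's median was 0% with or without H13, H3f3a and H1f0 (adjusted permutation p = 1.00).

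**Figure D3:**
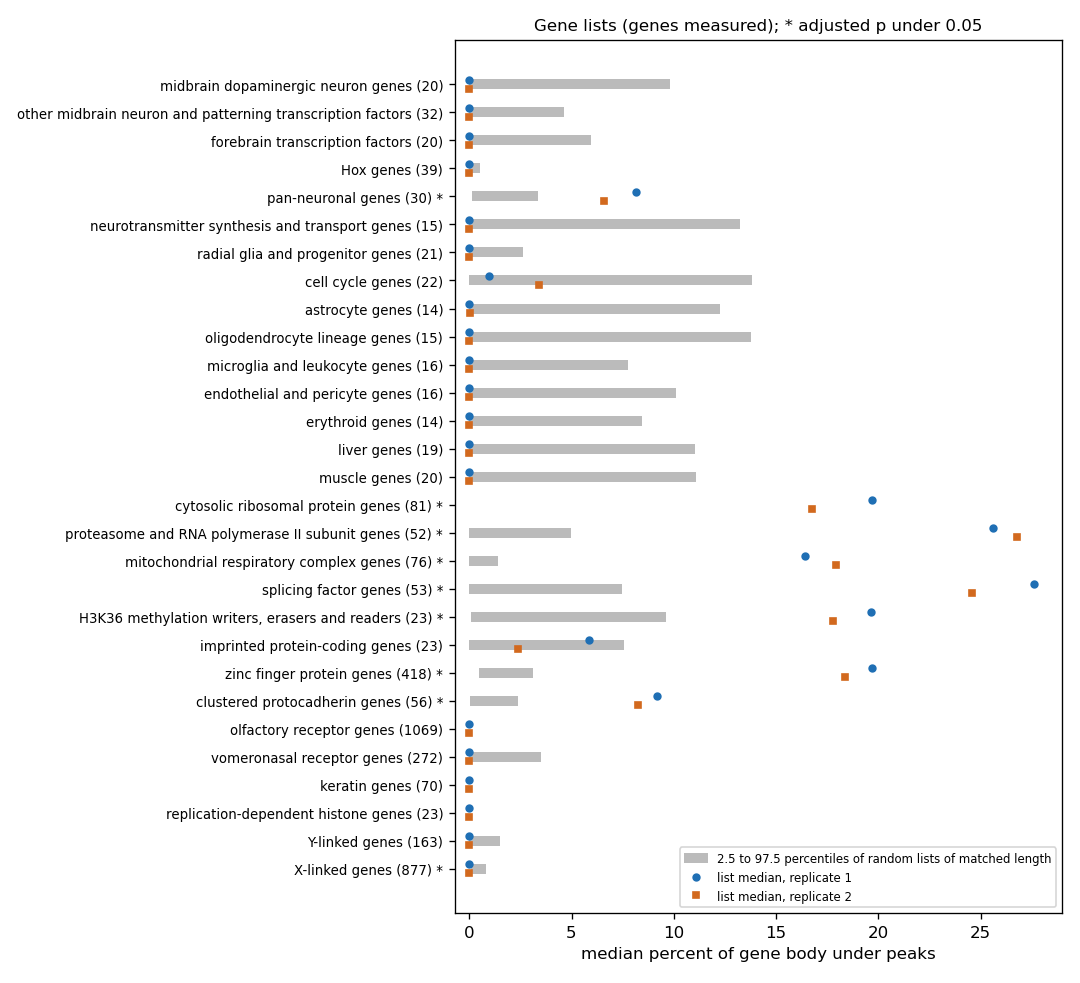
Median percent of the gene body under peaks (x axis) for each gene list (y axis, number of genes measured in parentheses), with circles for replicate 1, squares for replicate 2 and grey bars for the central 95% of random lists matched on length. The splicing factor, proteasome and RNA polymerase II, ribosomal, respiratory, zinc finger and H3K36 lists lie furthest to the right, and lists at 0% in both replicates include the dopaminergic and liver lists.

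Peaks stitched across gaps of up to 3 kb formed 32716 domains in replicate 1 and 30857 in replicate 2, and 9 of the 10 longest that both replicates shared lay over a single gene. Vps13d, a lipid transfer protein gene, held the longest at 154.2 kb in replicate 1 (chromosome 4, 145036445 to 145190673), of which peaks covered 40.7%, and a domain of 139.9 kb overlapped it in replicate 2. Mdn1, a ribosome assembly factor gene, had 115.3 kb and 112.6 kb, Hectd4 105.1 kb and 118.6 kb, Cplane1 101.2 kb and 103.3 kb, Ubr4 100.6 kb and 102.3 kb, Wdfy3 91.8 kb and 95.6 kb, and Trrap 90.3 kb in both. The domain over Fry measured 119 kb in replicate 1, where the longest overlapping domain of replicate 2 had 30.4 kb, and that over Xrn1 95.6 kb, where it had 58.4 kb. A domain of 107.6 kb on chromosome 18 in replicate 1 covered part of the Pcdhga cluster, where replicate 2 had 3 domains, the longest of 74.3 kb. Of 2 domains of 10 kb or more outside genes in replicate 1, the 1 shared with replicate 2 lay on chromosome 4 at 91211278 to 91230940, 19822 bases downstream of the end of Elavl2, a neuronal RNA-binding protein gene. It had 19.7 kb in replicate 1 and 9.38 kb in replicate 2. Stitching across 1 kb gave 61524 domains on average and across 10 kb 16566, against 31786 at 3 kb.

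Some genes differed in coverage between replicates. Psip1, a reader of H3K36 methylation, had 41.8% of its body covered in replicate 1 and 17.8% in replicate 2, the largest excess in replicate 1 among genes of at least 5 kb. Kdelc1, Gtpbp8, Kif20a and Dazap2 followed, with differences of 23.3, 22.1, 21.9 and 21.8 points. Psip1, Gtpbp8, Kif20a, Syvn1 and Arfip2 overlap another protein-coding gene. In the other direction Ajm1 had 2.76% in replicate 1 and 48.3% in replicate 2, and Syvn1, a ubiquitin ligase gene of the endoplasmic reticulum, 36.5% and 71.0%. Dus3l, Arfip2 and Ulk3 had 15.2%, 2.86% and 7.98% in replicate 1 and 47.5%, 32.3% and 37.3% in replicate 2. A gap of over 40 points separated the replicates in 11 genes, all higher in replicate 2, and 10 of them were shorter than 5 kb. Across marked genes the median of the SD between replicates was 3.44 points. These values compare single libraries, and no test between them was possible.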

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

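Both counts, of peaks in data that no comparison between genes used, were chosen after the coding gene results were seen. Of 6442 noncoding genes of at least 1 kb that overlap no protein-coding gene and whose coverage was compared with nothing else, 24 (0.373%) had at least 20% of the body under peaks in both replicates, among them Snhg1 at 44.1% ± 8.62, Snhg17 at 35.7% ± 0.646 and Snhg12 at 31.2% ± 10.7 (SD, n = 2). Of these 24 genes 19 lay within 5 kb of a protein-coding gene. The replicated list held 19 peaks on 8 scaffolds outside chromosomes 1 to 19, X and Y, with 40 such peaks in replicate 1 and 37 in replicate 2.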

How the results depend on the processing

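List means, matching on GC, the GC-limited exon comparisons, the changed histone list, autosomes alone and the gene length alternatives were chosen only after the results were seen. Of 75 alternative values for the main comparisons, 50 kept their direction and side of the threshold or moved by less than the limit set for them, among them all alternatives for peak bases in gene bodies, the 3′ shift and flanks. Gene list counts entered this tally for each setting as the total, those above and those below random lists. Its values are therefore not independent. The exon against intron difference turned to −0.598 points in genes whose exon GC was no higher than intron GC, where only 5 chromosomes could be tested, too few for any p under 0.0625 by the exact sign test. Simulated data with no preference gave −1.08 points. The difference stayed positive under its other alternatives, between 5.95 and 15.8 points. Marked genes numbered 5471 at 10% coverage and 529 at 40%, and 3533 to 3805 with either replicate left out. The share of genes of 10 to 50 kb marked went from 22.0% to 36.5% at 10%, 4.13% at 40%, 16.03% with −log10 q of at least 2 and 23.0% with the replicated list. Fold correlation was 0.322 for peaks overlapping by 50% of both, and both replicates touched 83.9% of replicated peaks by at least 1 base. Stitching across 1 kb gave 61524 domains and across 10 kb 16566. With list means, 23 lists passed the threshold, 15 of them below random lists, where medians gave 1 below. Means with GC matching gave 25, of which 17 below, and means without 1 replicate gave 22 to 23, of which 14 to 15 below. That 1 list, X-linked genes, left 0 below with −log10 q of at least 2, with the replicated list, among genes overlapping no other coding gene, with GC matching and with either replicate left out. Medians near 0 leave no room for a list to lie lower, which is the construction of that alternative, and the cause of the other shifts was not tested. Clustered protocadherin genes gave no value among genes free of overlap. Of 68 named genes above 0% in a replicate, 23 moved by more than 1 SD with −log10 q of at least 2 and 28 with the replicated list. Leaving out 1 of 2 replicates cannot move a value by more than 1 SD and was not counted. Cd68, the only marked microglia and leukocyte gene, fell from 47.4% to 16.98% with −log10 q of at least 2, and the cause was not tested. The median summit held 11 to 12 fragments, read totals were not given, and no alternative varied depth, so its part in the differences between replicates was not tested.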

Other observations

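The noncoding genes below, the Fisher test, the tests on last exons over all zinc finger genes and the comparison with X-linked genes holding peaks were chosen only after the coding results were seen, and the other tests were set out before their results were seen. Long noncoding RNA genes, picked by hand as known from brain or from imprinted regions, differed widely in coverage, and none of the 9 reached 20% in each replicate. Mirg, a microRNA host gene of that region, had 24.6% ± 8.53 of its body under peaks (SD, n = 2), Meg3 24.96% ± 10.8 and Rian 14.2% ± 0.474, while the protein-coding gene Dlk1 had 0%. Miat had 20.99% ± 5.73, Malat1 16.1% ± 5.66 and Rmst 12.1% ± 3.82. H19 had 0% in both replicates, Neat1 0.443% ± 0.626 and Pantr1 1.25% ± 0.164. None of these overlaps a protein-coding gene.

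Low coverage of X-linked genes was weighed against 3 explanations. Fewer broadly transcribed genes on the X chromosome was tested on 9 X-linked members of the ribosomal, proteasome, respiratory and splicing lists. They had a median of 0%, at the 0.005 percentile of draws from 253 autosomal members, with 0 of 9 marked against 122 of 253 (Fisher's exact test, p = 0.00401). These values argue against such a shortage as the whole cause, and a partial contribution stays open. Neither comparison was matched on gene length, although genes of 1 to 5 kb were marked less often (5.85%) than genes of 10 to 20 kb (22.7%). A single active X copy per cell stays open. The 7 genes known to escape X inactivation had a median of 9.15%. The upper end of the central 95% of medians, over lists of other X-linked genes of their length, was 2.91%. Kdm5c had 24.4%, Eif2s3x 21.4% and Ddx3x 18.7%, but Kdm6a had 2.12%, Pbdc1 2.11% and Mid1 1.63%, so members of the list differed widely. Against the 244 other X-linked genes with a peak in each replicate the median of the 7 escape genes lay at the 97.0 percentile (p = 0.0598, two-sided permutation test), so broad transcription of the escape genes may also contribute. Halved fragment numbers falling under the peak threshold also stay open. The fragments at the summit of each autosomal peak were halved with the background kept. Peaks whose summit still had p of 0.01 or less held 41.8% of autosomal peak bases. Each such peak kept its whole width, so bases lost around a summit were not taken away. X-linked genes had 22.5% of the coverage of autosomal genes of their length. The larger share was 1.86 times the smaller, within the limit set beforehand, and the remaining gap was left unexplained.

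High coverage of zinc finger protein genes was tested against copies and clusters. Reads shared between near-identical copies is argued against, as 361 genes without a copy of their last exon had a median of 20.9%, against 1.39% in random lists, and the 57 with a copy had 0%. Repeated counting of clusters is argued against too, since 1 gene from each of 161 clusters gave a median of 18.2%, against 1.17%. Coverage of the last exon as the whole excess is argued against, since over 417 zinc finger genes the body outside the last exon had a median of 10.03%, above 1.98%, the upper end of the central 95% of random lists of their length. Concentration of coverage on the last exon in marked zinc finger genes, the prediction set out beforehand, was nevertheless met. In 173 such genes the last exon exceeded the rest of the body by a median of 40.4 points. Other marked genes with last exons of like length gave 11.0 points, with 15.3 points as the upper end of the central 95% of draws. The rest of the body was 27.8% covered, against 30.8% in all other marked genes. The cause of the remaining excess stays open. No biological explanation could be compared between groups, since the design holds 1 group.

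Coverage differed between replicates in a way that followed base composition. Across 3064 marked genes, GC content and the excess of replicate 2 over replicate 1 had a Spearman's rho of 0.597, positive on all 19 chromosomes with at least 50 marked genes and between 0.422 and 0.705 there. The median excess was −3.41 points in the 766 genes with the lowest GC and 7.75 points in the 766 with the highest. Coverage was higher in replicate 1 in 41.4% of marked genes, which cannot by itself decide on greater sensitivity of replicate 2 alone. The median of replicate 1 minus replicate 2 was −1.52 points with an SD of 7.72 points over marked genes. A small gain of replicate 2 with such a spread would also leave many genes higher in replicate 1. Of the 766 genes with the lowest GC, however, 78.2% were higher in replicate 1. That share argues against greater sensitivity of replicate 2 alone for these genes. GC bias between libraries is a candidate explanation that stays open, and differences in library preparation or between the embryo pools were not tested.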
